A study of Mus musculus with 6 samples.

How the data were processed

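HSPCs were sorted by flow cytometry from control mice and from Med12Flox;MxCre mice of a B6/129 background, 4 days after pI:pC, per the labels' protocols. The labels do not give the genotype of the controls or say whether they carried Cre. Total RNA (5 ng) was amplified with the NuGEN Ovation system and biotin-labelled, per the labels' protocols. There were 6 arrays, 3 per group, and nothing in the labels says that each came from a separate animal, so p-values measure only the spread between these samples.

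The authors deposited 1 value per probe set and array, used here as linear signal intensity. The submitters' processing notes name RMA without a version, but the deposited values are linear: they run from 0 to 11134, and their mean after leaving out 2% at each end is 150.0 on every array. RMA gives log2 values and no zeros, so the method that made these intensities is not known here. The actin control probe sets had 3′ to 5′ ratios of 0.989 to 1.075 in controls and 1.006 to 1.081 in knockouts, and those of Gapdh were 1.381 to 1.522 and 1.391 to 1.773. Pearson correlations of log2 values across probe sets, which are not independent replicates, were 0.949 to 0.959 within controls, 0.965 to 0.972 within knockouts and 0.922 to 0.951 between groups. The number of arrays limits the precision.

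Values were taken as log2(signal + 16). The offset of 16 was chosen after zeros were seen in the files, and log2 differences on this scale understate the change of dim genes. Means and SDs in the text are of the deposited signals. Of 45101 probe sets, 64 controls were left out and 45037 were tested. The platform annotation of 2016 gave 34945 of these 1 gene symbol, 932 several and 9160 none; 284, 9 and 50 of the called probe sets fell in these classes. Genes were named only from probe sets with 1 symbol. Entrez numbers matched the RefSeq table of assembly GRCm38.p6, used for names only, for 34741 probe sets, and 0 symbols changed. Each of 18193 genes was represented by its probe set of highest mean, and gene calls use the p adjusted over all 45037 probe sets.

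The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (two-sided moderated test, 4 residual and 1.96 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparison, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The named genes were the Mediator kinase module, the 12 largest rises and 12 largest falls among genes past the threshold with groups not overlapping (leaving out symbols without an established name), and up to 4 members of each list by unadjusted p. Names outside that rule are given as chosen after their values were seen.

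The lists were the HSC-associated, haematopoietic transcription factor, cytokine and growth factor receptor, Mediator kinase module, Mediator core, interferon-stimulated, p53 target, BCL2 family and caspase, DNA replication, mitotic, ribosome biogenesis, oxidative phosphorylation, glycolysis, unfolded protein and ATF4, immediate early, WNT target, TGF-beta and BMP target, and cyclin and G0/G1 regulator genes. Further lists held genes of granulocyte-monocyte progenitors, neutrophils, macrophages, dendritic cells, early lymphoid cells, B cells, T, NK and innate lymphoid cells, erythroid cells, megakaryocytes, mast cells and basophils, eosinophils, endothelium, and stroma and osteolineage. Of 681 list entries 631 matched, 6 of them through an older symbol. The 31 lists were tested with camera (preset correlation 0.01) on 1 probe set per gene and adjusted together. Alternatives were camera with estimated correlations, fry and ranks. With estimated correlations camera also refers its statistic to the 4 residual degrees of freedom, so its p values rise even where the correlation is low. A sex-linked list was kept for checking the labels and not tested, and of its genes Xist and Eif2s3y are reported. Genes absent from the annotation were not analysed here. All 6 value columns were used (0 left out).

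Alternatives were a trended and robust prior, array weights, a block on the replicate number, median centring, quantile and loess normalization, leaving out each array, filters on dim probe sets, fold cut-offs, a looser threshold and a plain equal-variance test. Other offsets, a floor at 16, lists without shared genes, the kinase module list without Med12, and the trended prior together with a filter were added after the data were seen. The steps were tested on simulated data: of 200 changed probe sets among 45037, limma recovered 18% and 16% at log2 differences of 1 and -1, and 50% and 46% at 2 and -2. It called 0 unchanged probe sets, of which 5.93% had an unadjusted p under 0.05. The recovered shares do not give the power of the measured comparison, where 7067 probe sets had an unadjusted p under 0.05 in limma's test. With more changed probe sets the Benjamini-Hochberg cut is less strict. On 18193 simulated genes camera called 0 unchanged lists, and a list of 25 genes shifted by 0.5 had an adjusted p of 7.64e-17. The simulated genes were drawn independently, while correlations estimated for the measured lists reached 0.385. The simulation therefore does not test camera's false calls among correlated genes. Python 3.11.15, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0 were also used.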

Results

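Gene expression was measured in haematopoietic stem and progenitor cells (HSPCs) sorted from the bone marrow of control mice and of mice in which the Med12 gene had been deleted. The sort gate took marrow cells that lacked lineage markers and carried c-Kit and Sca1, which holds stem cells and multipotent progenitors. Med12 encodes a subunit of the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II. The knockout mice carried a floxed Med12 allele and Mx-Cre, a recombinase switched on by interferon. Cells of both groups were taken 4 days after pI:pC, a synthetic double-stranded RNA that induces interferon. Each group had 3 arrays, named by group and replicate number. The median signal per array was 26.8, 26.9 and 26.7 in controls and 20.6, 21.3 and 16.6 in knockouts. Signals under 16 made up 42.3%, 42.0% and 41.6% of probe sets on the control arrays and 46.3%, 45.5% and 49.5% on the knockout arrays. Xist, the RNA of the inactive X chromosome, had signals of 5.2 to 8.3 in controls and 2.2 to 16 in knockouts. The Y-linked gene Eif2s3y had signals of 314.9 to 507.9 in controls and 384.2 to 644.1 in knockouts.

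The comparison asked which gene programs depend on Med12 in these cells, and Med12 itself was examined before the other genes. Its mean signal was 519 ± 287 in controls and 92.0 ± 7.43 in knockouts (SD, n = 3 each). The signals of 89.1, 100.4 and 86.4 on the knockout arrays all lay below the control signals of 278.6, 837.4 and 441.6. The log2 difference was -2.17 (SE 0.38), and limma's adjusted p of 0.0796 did not pass the threshold of 0.05. Of the remaining 6 members of the Mediator kinase module list, 5 had lower and 1 had higher log2 signal in knockouts, and none passed. The Med12 paralog Med12l had a log2 difference of -1.25 (adjusted p = 0.294), and its other probe sets were at 0.31 and -0.30. Med13l, a scaffold subunit of the module, had a log2 difference of -1.03 (adjusted p = 0.108), although 1 of its 3 probe sets passed. The differences were -0.34 for Med13, -0.34 for the kinase Cdk19 and -0.29 for cyclin C (Ccnc), whose 5 probe sets did not all share that sign. The kinase Cdk8 had a log2 difference of 0.14 (SE 0.64), which turned to -0.04 with array weights and to -0.52 without control replicate 3. Ccnc likewise turned to 0.06 without control replicate 2. Adjusted over the list alone, Med12 and Med13l fell. The median of the module was -0.29 relative to all genes, or -0.43 after quantile normalization, and limma's camera test gave an adjusted p of 0.0154, or adjusted p = 0.223 with an estimated correlation. The list holds the deleted gene itself, and without Med12 the other 6 members had a median of -0.28 and did not pass (adjusted p = 0.0676, or 0.270 with an estimated correlation). The call with Med12 was also lost without control replicate 2 (adjusted p = 0.0558). Med12 was read by a single probe set whose place relative to the deleted part of the gene is not known here, so its level checks the labels only if the probe set lies within that part. Med12 did pass with a trended, robust variance prior (adjusted p = 0.0339) or without the dimmest 25% of probe sets (adjusted p = 0.0273), and its adjusted p ranged from 0.00649 to 0.248 over all settings tried.

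Genes typical of myeloid and lymphoid progenitors were among the largest falls in Med12 knockouts. The red cell genes Kel and Rhag were among the 12 largest rises, none of which is on the erythroid list. Of 18193 genes, each represented by 1 probe set, 64 rose and 116 fell in Med12 knockouts. Dntt, the terminal transferase of early lymphocytes, fell from a mean signal of 1568 ± 269 to 18.5 ± 14.4 (SD, n = 3 each), a log2 difference of -5.59 (SE 0.32; adjusted p = 0.0163). Elane, the neutrophil elastase gene, fell from 1566 ± 640 to 18.7 ± 6.60, a log2 difference of -5.44 (SE 0.35; adjusted p = 0.0199). Next by size among named genes came Prg2, an eosinophil granule protein (-4.62), the macrophage growth factor receptor Csf1r (-4.61) and the chemokine Ccl3 (-4.60). The transcription factor Irf8, which directs monocyte and dendritic cell fates, fell by 4.06 on the log2 scale. The monocyte chemokine receptor Ccr2 (-4.02), the chromatin organiser Satb1 (-3.93) and the interleukin-7 receptor Il7r (-3.85) also fell. Sdc1 (-3.80), Ly86 (-3.74) and the flippase gene Atp8b4 (-3.72) completed the 12 largest falls, whose adjusted p values lay between 0.0163 and 0.0496.

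Among the 12 largest rises, Alox5, the 5-lipoxygenase of leukotriene synthesis, went from 11.3 ± 11.2 to 483 ± 209 (log2 4.19; SE 0.39; adjusted p = 0.0302). Sapcd1 followed at 3.49. The Kell blood group gene Kel rose by 3.46 (log2; SE 0.48; adjusted p = 0.0494), and the Rh-associated glycoprotein gene Rhag rose by 2.87, from 29.7 ± 9.17 to 318 ± 61.4. The adhesion gene Parvb rose by 3.23 and Bex4 by 2.88. The mast cell chymase gene Cma1 rose by 2.56 and the interferon-inducible exonuclease gene Isg20 by 2.37, from 166 ± 31.1 to 928 ± 195. Asb17 (2.47), Clca3a1 (2.47), Epdr1 (2.38) and Rec114 (2.57) were the others. The second probe set of Rec114 had the opposite sign, with a log2 difference of -0.25.

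Counted by probe set, 343 of 45037 passed limma's test, 99 higher and 244 lower in knockouts, and 7067 had an unadjusted p under 0.05. In all 180 gene calls the 3 knockout values lay on one side of the 3 control values, as they did for 20.9% of all probe sets, where chance gives 10%. The count rested on having all 6 arrays: 8 probe sets passed without control replicate 1, 8 without control replicate 2, 10 without control replicate 3 and 3 without knockout replicate 2. With limma, 0 passed without knockout replicate 1, where 6219 had an unadjusted p under 0.05, and 0 without knockout replicate 3, where 5340 did. The median difference over all genes was -0.05 (log2), and centring each array on its median moved it to 0.22 and the share of higher calls from 28.9% to 62.2%.

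**Figure D1:**
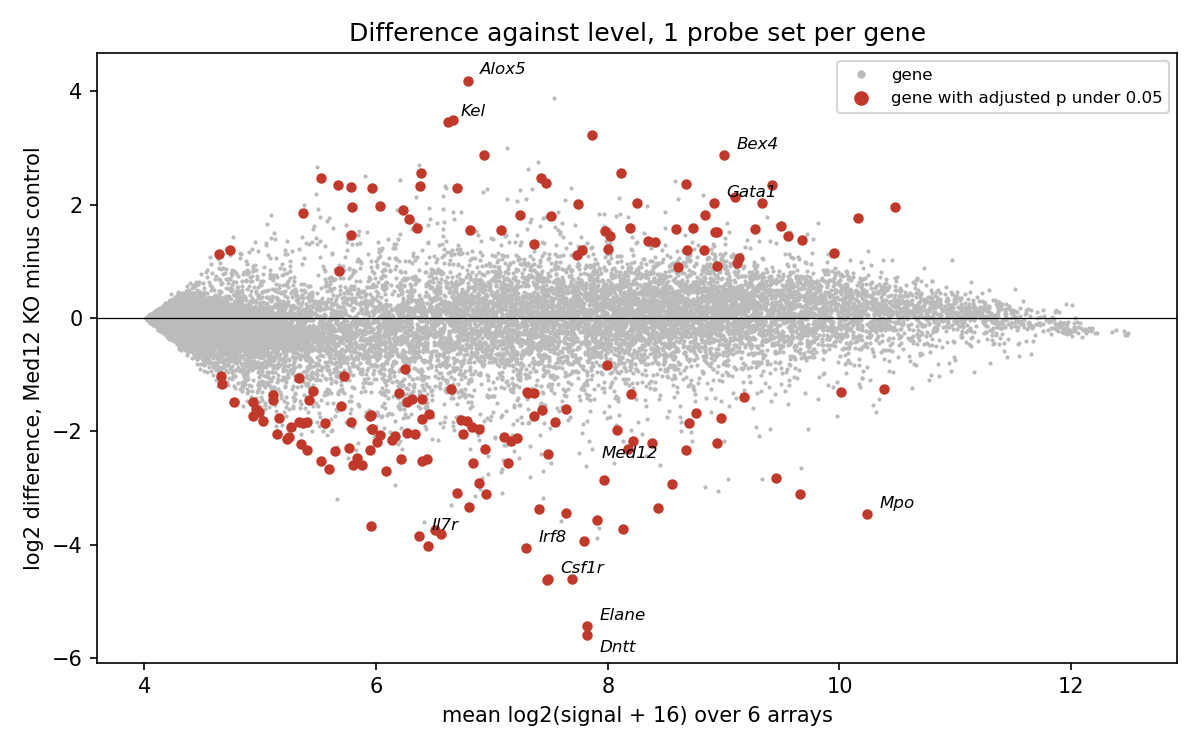
Log2 difference, Med12 knockout minus control (vertical), against mean log2(signal + 16) over the 6 arrays (horizontal), with 1 point per gene for 18193 genes. Red points are the 180 genes with adjusted p under 0.05, with Dntt at -5.59 and Elane at -5.44 at the bottom and Alox5 at 4.19 at the top of them; Med12, at -2.17, is grey.

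Genes of granulocyte-monocyte progenitors were lower as a group. Of 18 measured, 7 fell, 0 rose and 11 did not pass; adjusted over the list alone, 15 fell. Mpo, the myeloperoxidase gene, fell from 4066 ± 982 to 383 ± 200 (log2 -3.46; SE 0.40; adjusted p = 0.0363). The granule protease genes Ctsg (-3.10; adjusted p = 0.0343) and Elane fell with it, as did Irf8 and Csf1r. Prtn3 (-2.82) and Hk3 (-2.41), named because they complete the 7, were chosen after their values were seen. The median of the group was -2.22 relative to all genes, with a camera adjusted p of 2.83e-13. That p rose to an adjusted p = 0.128 with an estimated correlation. Mature cells of the same lineages gave smaller group medians, a contrast that was not tested. Some of their genes were dim, such as Camp (27.1 ± 3.99 to 14.3 ± 3.13), and the added 16 leaves such genes little room to fall. The mature neutrophil list (15 measured) had a median of -0.46 and a camera adjusted p of 0.0423, or adjusted p = 0.240 with an estimated correlation. None of its members passed, including the chemokine receptor Cxcr2 (-1.22; adjusted p = 0.150). Of the 16 macrophage genes, the complement gene C1qa fell (-1.01; adjusted p = 0.0363) and 15 did not pass, and the list did not differ from other genes (camera adjusted p = 0.374). Of 6 eosinophil genes, Prg2 and Prg3 (30.9 ± 12.3 to 0.367 ± 0.0577, log2 -1.49, adjusted p = 0.0486) fell and 4 did not pass. The sizes given for C1qa and Prg3 depend on the added 16. Adjusted over the list alone, the eosinophil peroxidase gene Epx (-1.90) made a total of 3 that fell. The eosinophil list had a median of -0.74 and a camera adjusted p of 0.0120, or adjusted p = 0.128 with an estimated correlation. The neutrophil call was lost without control replicate 2 (adjusted p = 0.125), without knockout replicate 1 (0.134) and after quantile (0.0654) or loess (0.0918) normalization. It was also lost without the dimmer 50% of probe sets (0.0635), with the mean of all probe sets of a gene (0.0728) and with 64 added before log2 (0.0567), and the eosinophil call was lost on ranks (0.112).

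Early lymphoid genes were lower in every member measured. Of 17, 6 fell and 11 did not pass; adjusted over the list alone, all 17 fell. Besides Dntt, Il7r and Satb1, the recombinase gene Rag2 fell from 121 ± 34.2 to 8.40 ± 1.83 (log2 -2.46; SE 0.22; adjusted p = 0.0293). The adaptor gene Lax1 fell by 1.95 on the log2 scale (adjusted p = 0.0199). Ccr7 (-1.72), chosen after its values were seen, was the remaining call. The cytokine receptor Flt3, also chosen after its values were seen, went from 924 ± 233 to 60.7 ± 58.2 and missed the threshold (log2 -3.87; adjusted p = 0.0573). The group median was -1.86 relative to all genes and the camera adjusted p was 6.08e-17, or adjusted p = 0.123 with an estimated correlation. Genes of later lymphoid and dendritic cells showed no calls over all genes. The 15 B cell genes had a median of -0.58 (camera adjusted p = 0.00886, or adjusted p = 0.352 with an estimated correlation). The B cell antigen gene Cd72 was at -2.05 (adjusted p = 0.0770) and was the only one to fall adjusted over the list alone. The 17 genes of T, NK and innate lymphoid cells had a median of -0.29, or -0.18 after loess normalization (camera adjusted p = 0.0274, or adjusted p = 0.372 with an estimated correlation), with Ccl5 at -1.70 and Gzma at -1.69, and none fell adjusted over the list alone. The 16 dendritic cell genes had a median of -0.31 (camera adjusted p = 0.0359, or adjusted p = 0.303 with an estimated correlation). Ccr9 (-1.66) and Tcf4 (-1.14) fell adjusted over that list alone. These 3 calls were lost without control replicate 2 (adjusted p = 0.0550, 0.0873 and 0.143 for B, T and NK, and dendritic cells) and without knockout replicate 3 (0.0525, 0.131 and 0.0576). The T and NK call was also lost without control replicate 3 (0.0538) and after loess normalization (0.0533), and the dendritic call without knockout replicate 2 (0.0662) and under 5 of the other settings tried (0.0560 to 0.219).

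The receptor and transcription factor lists of blood progenitors had negative medians, although few of their members passed. Of 25 cytokine and growth factor receptor genes, Il7r, Csf1r and the interleukin-1 receptor Il1r1 (-1.32; adjusted p = 0.0404) fell, the erythropoietin receptor Epor rose, and 21 did not pass. Il7r is also on the early lymphoid list and Csf1r on the granulocyte-monocyte list. Adjusted over the receptor list alone, 12 fell and 1 rose. The median was -0.68 relative to all genes (camera adjusted p = 1.30e-05, or adjusted p = 0.123 with an estimated correlation). Of 29 haematopoietic transcription factor genes, 25 were lower, or 19 after median centring, and 0 passed over all genes, against 10 that fell and 1 that rose, Zfpm1 (0.65; chosen after its values were seen), adjusted over the list alone. Gfi1, a repressor needed for granulocyte and lymphoid fates, had signals of 860 ± 70.6 and 74.0 ± 74.0 (log2 -3.70; adjusted p = 0.0906). The myeloid factor Cebpa was at -1.82 (adjusted p = 0.0971), Erg at -1.09 (0.129) and Etv6 at -1.04 (0.0800). The list median was -0.36 (camera adjusted p = 0.000413, or adjusted p = 0.128 with an estimated correlation).

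Erythroid genes were higher as a group. Of 23 measured, 6 rose and 17 did not pass; adjusted over the list alone, 15 rose and 1, Slc4a1, fell. Gata1, the master transcription factor of red cells and megakaryocytes, rose from 230 ± 70.1 to 975.4 ± 221 (log2 2.03; SE 0.26; adjusted p = 0.0424). Epor rose from 93.6 ± 31.7 to 420 ± 86.0 (log2 2.01; SE 0.27; adjusted p = 0.0471). The carbonic anhydrase gene Car1 rose by 1.76, the biliverdin reductase gene Blvrb by 1.81 and the membrane skeleton gene Add2 by 1.59. Klf1, the erythroid factor that completes the 6, rose by 2.03 (adjusted p = 0.0490) and was chosen after its values were seen. The anion exchanger gene Slc4a1, abundant in maturing red cells and also chosen after its values were seen, was at -1.60 (adjusted p = 0.260). The group median was 1.44 relative to all genes (camera adjusted p = 3.79e-13, or adjusted p = 0.128 with an estimated correlation). The megakaryocyte integrin gene Itga2b rose from 348 ± 66.2 to 1057 ± 179 (log2 1.56; adjusted p = 0.0431) and the other 20 megakaryocyte genes did not pass. Adjusted over that list alone 4 rose, the others being Gp1bb (1.61), Cd9 (1.06) and Rab27b (0.75). The megakaryocyte median was 0.70 (camera adjusted p = 4.66e-05, or adjusted p = 0.281 with an estimated correlation). Of 15 mast cell and basophil genes Cma1 rose and 14 did not pass, and adjusted over the list alone the granzyme gene Gzmb (1.68) was added. The IgE receptor genes Fcer1a (2.29; adjusted p = 0.196) and Ms4a2 (1.21; adjusted p = 0.251) did not pass, although 1 of the 2 Ms4a2 probe sets did. The mast cell list had a median of 0.42 (camera adjusted p = 0.00839, or adjusted p = 0.128 with an estimated correlation).

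**Figure D2:**
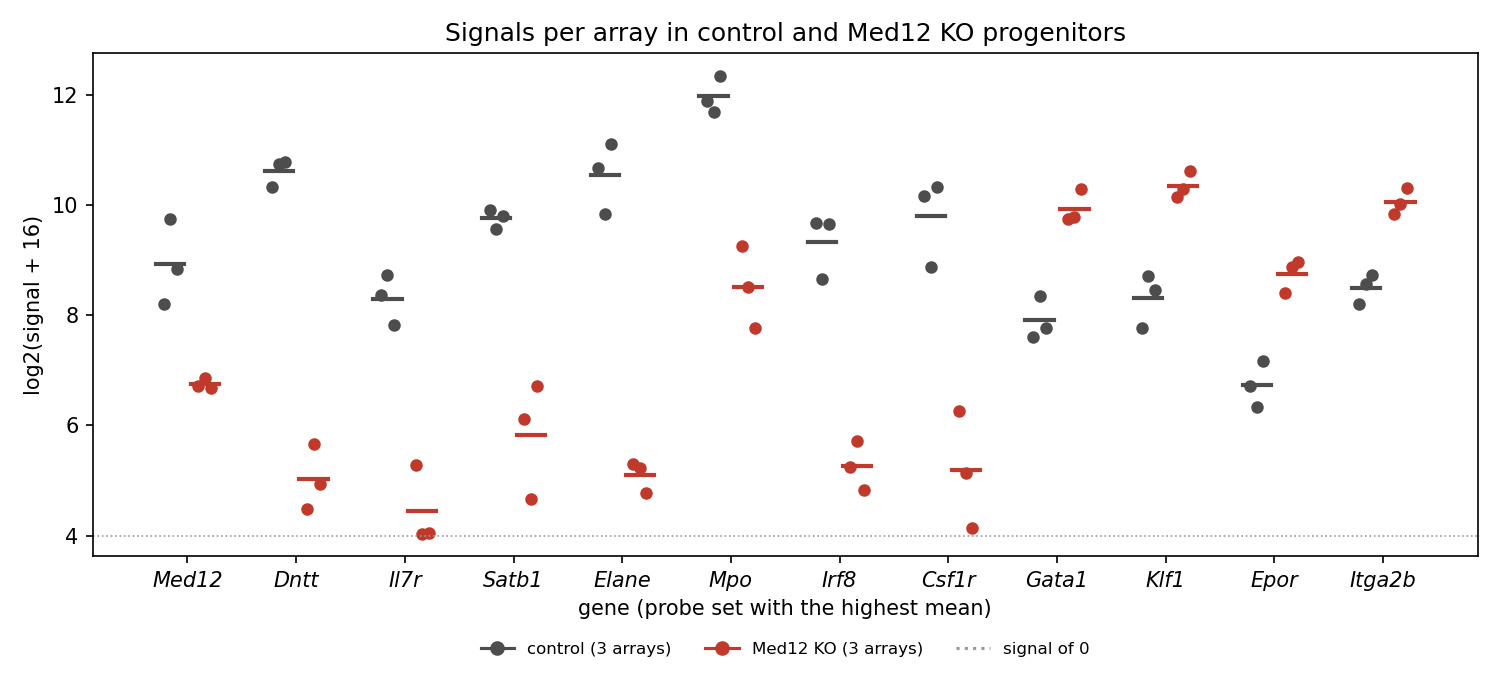
Log2(signal + 16) of 12 genes on each of the 3 control and 3 Med12 knockout arrays, as points, with bars at the group means and a dotted line at a signal of 0. For Dntt, Il7r, Satb1, Elane, Mpo, Irf8, Csf1r and Med12 every knockout array lay below every control array, and for Gata1, Klf1, Epor and Itga2b every knockout array lay above.

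Genes associated with haematopoietic stem cells did not move as a group. Of 30 measured, 2 fell and 28 did not pass. Hlf, a transcription factor of stem cells, fell from 645 ± 252 to 126 ± 21.9 (log2 -2.17; SE 0.29; adjusted p = 0.0479). The GTPase gene Gimap6 fell from 1055 ± 227 to 218 ± 56.6 (log2 -2.20; SE 0.26; adjusted p = 0.0376). Adjusted over the list alone, Txnip (-1.16) and Robo4 (-2.13; chosen after its values were seen) also fell, and the repressor gene Gfi1b (0.76) rose. The median was -0.08 relative to all genes (camera adjusted p = 0.224), or -0.13 after quantile and -0.14 after loess normalization. Of the 30 genes 20 were lower, and 13 after median centring. That p passed after median centring (0.00926), without control replicate 3 (0.0137) and without the dimmer 50% of probe sets (0.0440), and was 0.996 without control replicate 2, where the direction turned. Genes of cells outside the blood lineages did not differ as groups either. Of the 16 endothelial genes 13 were lower, but 6, 7 and 9 after median centring, quantile and loess normalization, and the median was -0.10 (camera adjusted p = 0.256), or -0.02 and -0.03 after quantile and loess normalization. Egfl7 was at -0.60, Nos3 at -0.53 and Ptprb at -0.34, while Plvap was at 1.59 (adjusted p = 0.218). The 15 stromal and osteolineage genes had a median of 0.09 (camera adjusted p = 0.687), with Col1a2 at 0.87 (adjusted p = 0.190). No member of either list passed over all genes or adjusted over the list alone.

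Genes of cell division and biosynthesis were higher by small amounts in many members at the same time. All 29 mitotic genes, or 28 after loess normalization, had higher log2 signal in knockouts; 0 passed over all genes, and 5 rose adjusted over the list alone. The mitotic kinase gene Cdk1 had signals of 658 ± 153 in controls and 1418 ± 229 in knockouts (log2 1.10; adjusted p = 0.0981). The others were Anln (1.10), Plk1 (0.85), Ckap2l (0.65) and Cdc20 (0.88; chosen after its values were seen). The mitotic median was 0.69 relative to all genes (camera adjusted p = 2.83e-13, or adjusted p = 0.123 with an estimated correlation). Of 28 DNA replication genes 22 were higher, with a median of 0.36 (camera adjusted p = 0.000192, or adjusted p = 0.128 with an estimated correlation). The ribonucleotide reductase gene Rrm2 was at 0.65 and cyclin E1 (Ccne1) at 0.75, while thymidylate synthase (Tyms) was at -0.51, and none rose or fell adjusted over the list alone. Of 30 ribosome biogenesis genes 27 were higher, with a median of 0.40 (camera adjusted p = 4.30e-08, or adjusted p = 0.128 with an estimated correlation). Nolc1 (0.84), Grwd1 (1.31) and Rrp9 (0.65) rose adjusted over that list alone. Of 27 oxidative phosphorylation genes 24 were higher, with a median of 0.32, or 0.19 after loess normalization (camera adjusted p = 1.19e-05, or adjusted p = 0.281 with an estimated correlation). Uqcrc2 was at 0.67 and Ndufa9 at 0.52, and none rose adjusted over the list alone. Of 26 core Mediator subunit genes 22 were higher, with a median of 0.49 (camera adjusted p = 2.44e-05, or adjusted p = 0.128 with an estimated correlation). Med14, the scaffold of the complex, was at 0.87 (adjusted p = 0.140), Med8 at 1.58 and Med10 at 1.24, and none rose adjusted over the list alone. Of the 5 probe sets of Med14 2 were lower (-0.26 and -0.61), and the second probe set of Med8 was at -0.07. The 18 cyclins, cyclin-dependent kinase inhibitors and G0/G1 regulators had a median of 0.27 (camera adjusted p = 0.00849, or adjusted p = 0.128 with an estimated correlation). Members of opposite action were higher together, since Cdkn2c (0.84) and Rb1 (1.01) restrain the cycle while Ccnd3 (0.81) drives it; with E2f4 (0.92) they made the 4 that rose adjusted over that list alone. The cyclin list call was lost after quantile (0.0654) or loess (0.0533) normalization.

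Signalling and stress genes gave no call over all genes in any list. Of 33 interferon-stimulated genes 23 were higher, with a median of 0.50 (camera adjusted p = 0.000425, or adjusted p = 0.251 with an estimated correlation). Cmpk2 had signals of 76.4 ± 12.6 and 266 ± 96.3 (log2 1.57; adjusted p = 0.0761), and it rose adjusted over the list alone with Usp18 (1.12), Gbp7 (0.64) and Zbp1 (1.53). Of 22 immediate early genes 18 were lower, with a median of -0.62 (camera adjusted p = 0.00571, or adjusted p = 0.372 with an estimated correlation). The RNA-decay gene Zfp36 (-1.53) and the phosphatase gene Dusp2 (-1.77) fell and the heat shock gene Hspa1b (3.89) rose adjusted over that list alone. Of 15 TGF-beta and BMP targets 13 were lower, or 10 after median centring, with a median of -0.42, or -0.28 after loess normalization (camera adjusted p = 0.0321, or adjusted p = 0.291 with an estimated correlation), and Tgif1 (-1.36) and Ltbp3 (-1.03) fell adjusted over the list alone. That call was lost without control replicate 2 (0.0873), knockout replicate 2 (0.121) or knockout replicate 3 (0.0544), and without genes shared with other lists (0.0518). The 15 WNT targets had a median of -0.24 (camera adjusted p = 0.0724), or -0.08 after quantile and -0.10 after loess normalization, with Lgr5 at -0.48, and none fell adjusted over the list alone. That list passed without control replicate 2 (0.0349), on ranks (0.0492) and with signals floored at 16 (0.0481). The 26 p53 targets did not differ from other genes (camera adjusted p = 0.626) but held members of both signs. Adjusted over the list alone Trp53inp1 (-2.16), Sesn1 (-1.17) and Ddit4 (-0.90) fell while Ckap2 (1.18), Phlda3 (0.82) and Ccng1 (0.50) rose, Ddit4 and Ccng1 being chosen after their values were seen. The other probe set of Trp53inp1, dimmer and not used for the gene call, did pass limma's test over all probe sets (-2.43, adjusted p = 0.0268). Glycolysis genes (16 measured; camera adjusted p = 0.5003) likewise held a rise in Hk1 (0.84) and falls in Aldoc (-1.23) and Pkm (-0.47) adjusted over the list alone. Neither the 22 unfolded protein and ATF4 response genes (camera adjusted p = 0.610), with Trib3 at -1.09, nor the 19 BCL2 family and caspase genes (camera adjusted p = 0.256), with Mcl1 at -0.43, had a member that passed over all genes or over the list alone. In the p53, glycolysis, unfolded protein and stromal lists the mean difference was negative (-0.03, -0.02, -0.05 and -0.0042) while camera's direction was up. Camera compares a list with the other genes, and relative to all genes these means were positive (0.05, 0.06, 0.03 and 0.08). Among these lists the median was negative in the p53 list alone (-0.0022).

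Among the other genes named from the lists, probe sets of opposite sign were also found for Tyms, Anln, Ccnd3, Rb1, Rab27b, Lgr5, Ccr9, Ptprb, Col1a2 and Slc4a1, and the values given are those of the probe set with the highest mean.

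**Figure D3:**
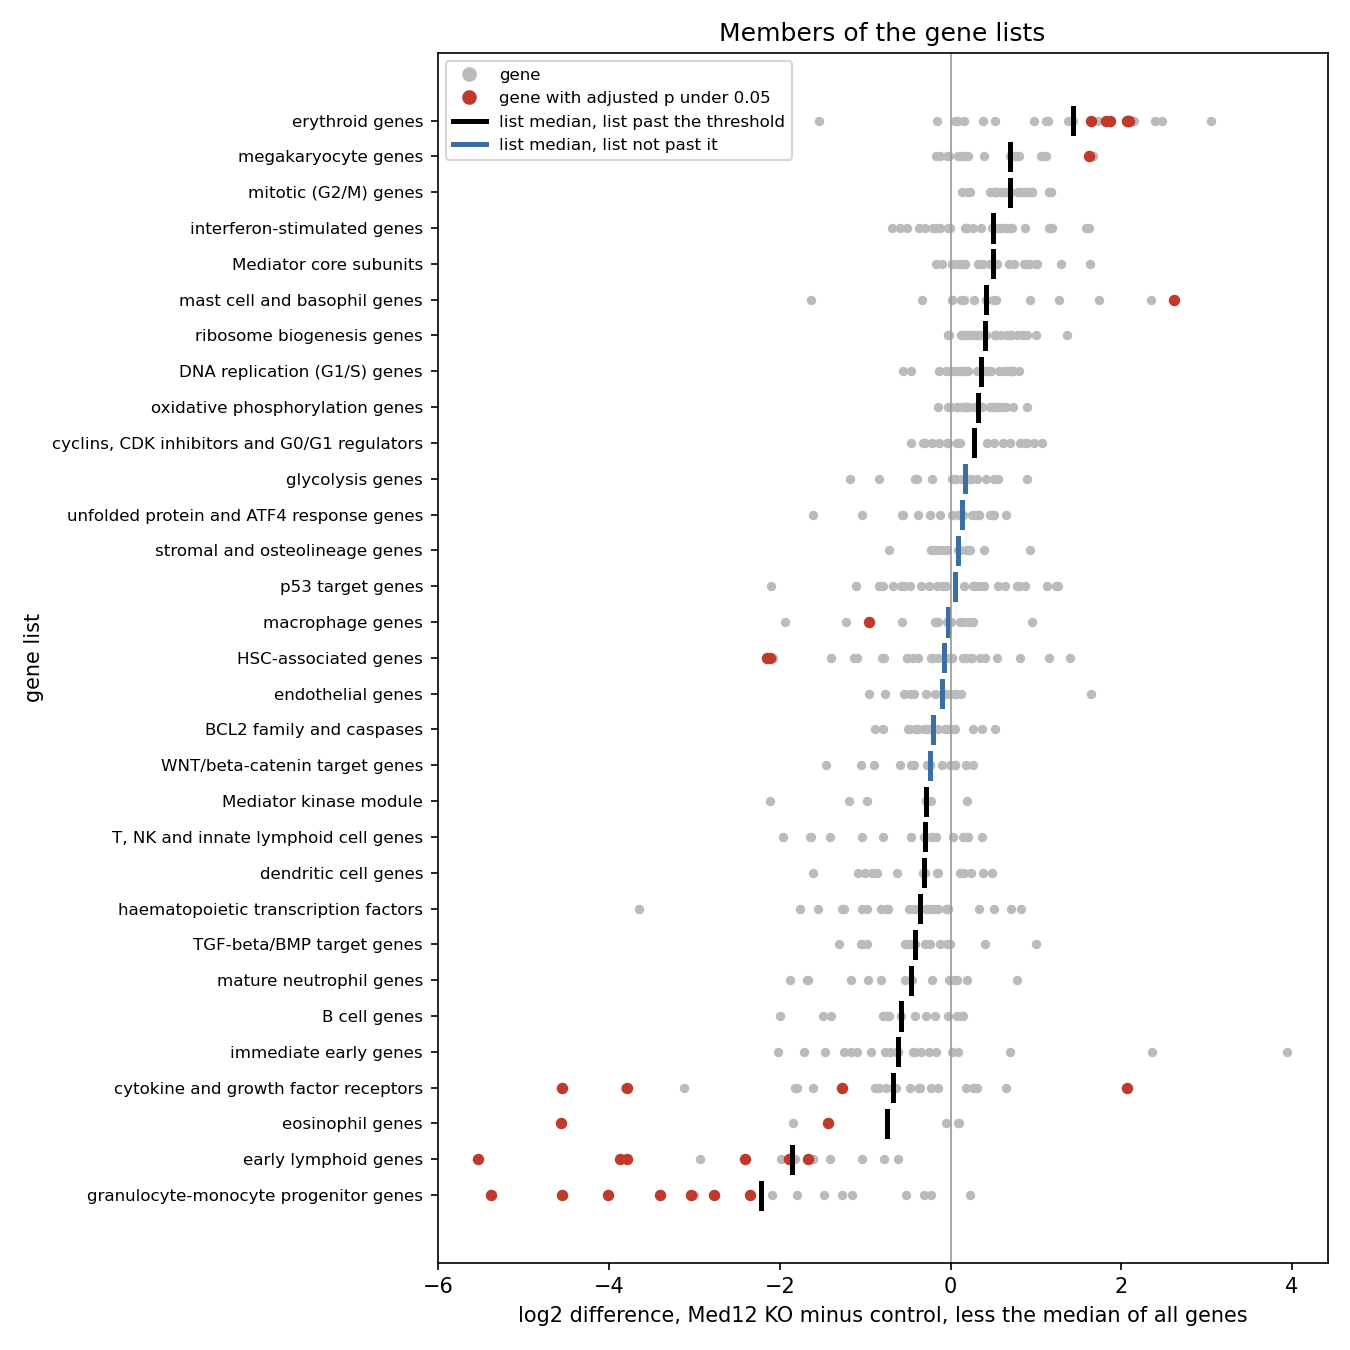
Log2 difference, Med12 knockout minus control, less the median of all genes (horizontal) for each member of 31 gene lists (vertical), with genes of adjusted p under 0.05 in red and list medians as black bars where camera passed and blue bars where it did not. Early lymphoid (-1.86) and granulocyte-monocyte progenitor genes (-2.22) lay to the left and erythroid genes (1.44) to the right.

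By limma's camera with its preset correlation, 10 lists were higher and 12 lower. With the correlation estimated from the arrays, 0 of these 22 calls held. Under that setting camera also refers its statistic to the 4 residual degrees of freedom, a far stricter reference than under the preset. The loss cannot be laid to correlation alone, since lists with estimates below the preset 0.01 lost their calls too. These were the receptor (0.0057), cyclin (-0.048), mast cell (-0.051) and eosinophil (-0.074) lists. By limma's fry, which asks only whether genes move one way, 15 lists passed. By fry the kinase module, interferon, oxidative phosphorylation, immediate early, TGF-beta, dendritic, B cell, T and NK, and megakaryocyte lists did not pass, at adjusted p values from 0.0545 to 0.114, while the WNT (0.0310) and macrophage (0.0212) lists did.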

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

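The tests weighed here were chosen only after the result was seen, except the splits for gene lists and the brightness-matched random lists. A signal outside the tested probe sets came from the array's mouse control probe sets. Of 19 such sets, those named TransRecMur 5 and TransRecMur M were higher on every knockout array than on any control array, with ratios of mean signal of 2.402 (257 ± 18.2 to 616 ± 108) and 1.88 (130 ± 39.7 to 243 ± 41.6; SD, n = 3 each). The set named MURINE_b1 went the other way without overlap, from 1890 ± 87.3 to 1509 ± 29.7. The groups did not overlap in 3 of the 19, beside 20.9% of all tested probe sets, where chance gives 10%. TransRecMur 3 went from 283 ± 135 to 649 ± 396, with overlap. The names point to the mouse transferrin receptor, whose own gene, Tfrc, had signals of 555 ± 299 and 1237 ± 785 and did not pass (log2 1.08; adjusted p = 0.395).

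Granulocyte-monocyte and early lymphoid genes were lower and erythroid genes higher in Med12 knockouts. Scaling by the authors as the whole cause is argued against, since the 3 lists kept direction and camera calls in 6 of 6 combinations with quantile and loess normalization, although these calls were lost with an estimated correlation (adjusted p = 0.128, 0.123 and 0.128). Mature red cells in the knockout sort, which a gate on lineage-negative, c-Kit-positive cells is meant to leave out, stay open for the erythroid rise. The 7 transcripts abundant in such cells had a median difference of 0.0987, beside 1.38 for the erythroid list. Spread over the 7 genes, not over arrays, gave a standard error of the mean of 0.348. Only 2 of the 7 transcripts reached a mean signal of 100, and they went opposite ways. They were Hba-a2 (2277 ± 798 to 2022 ± 469) and Hbb-b2 (log2 1.13, with its other probe set of opposite sign). For the falls, dilution by cells that also lack HSC-associated genes, mature red cells among them, was not decided. The median of those genes lay 1.78 (log2) above the nearer of both lists with all arrays, and 1.40 in the lowest fit without 1 array. Their brightness was not checked, and dim genes can show little fall on this scale. Gimap6 (-2.20) and Hlf (-2.17) fell about as far as the medians of both lists (-2.28 and -1.91), while Txnip was at -1.16 and Gfi1b at 0.76. Without the dimmer 50% of probe sets camera called the HSC-associated list lower (adjusted p = 0.0440). Med12 loss may act on transcription within each cell or on the mix of stem cells and primed progenitors in the gate, and since the controls' genotype is not given, Cre or strain background stays open too, for this and every other difference; none of these was tested.

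Mitotic, DNA replication, ribosome biogenesis, oxidative phosphorylation and Mediator core genes were higher in knockouts, each by a small median. A shift shared by probe sets of like brightness is argued against as the whole cause. Medians of 10000 random lists matched on mean signal centred on 0.05 to 0.09, beside 0.27 to 0.64 for the 5 lists. The lowest percentile of the 5 list medians was 99.85, for oxidative phosphorylation (0.27, beside 0.06). That percentile may be too high, since random members were drawn independently while the 5 lists had estimated correlations of 0.058 to 0.33. Scaling as the whole cause is argued against by 10 of 10 combinations of list with quantile or loess normalization that kept direction and call, although the oxidative phosphorylation median relative to all genes shrank from 0.32 to 0.19 with loess, and probe set choice by a highest adjusted p of 0.000446 with the mean of all probe sets of a gene. The calls were made with camera's preset correlation, and none held with an estimated one. Lists whose estimate lay below the preset 0.01 lost their calls as well, so the loss cannot be laid to correlation alone. The estimated setting also rests on the 4 residual degrees of freedom, which by itself raises the p values. A larger share of dividing cells in the knockout gate may underlie part of the pattern, as an untested hypothesis.

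The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. In 1 of the 10 splits, the real one, as many as 343 probe sets passed, and the highest of the others gave 0. For gene lists 1 of the 10, again the real one, gave 22, and the highest of the others gave 14. Every other split has controls and knockouts on each side, so part of the real difference remains and also widens the spread within sides. The counts of those splits are therefore no reference for a state without difference.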

How the results depend on the processing

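Chosen after the data were seen were the offsets of 1 and 64, the floor of 16, the lists without shared genes, the kinase module list without Med12 and the trended prior after a filter. The 343 called probe sets kept their sign under all settings that fitted them (306 of them with the dimmer 50% left out). A change of sign was possible only with another scaling, array weights, offset or floor, or without 1 array where groups overlapped. The number of calls moved to 693 with median centring (62.2% higher, against 28.9%) and to 154 with treat against 1.2-fold. Without the dimmest 25% and 50% of probe sets, where fewer were tested, it was 715 and 755. It was 1159 at an adjusted p under 0.1 and 1212 with the trended, robust prior after the 50% filter. Offset 1 gave 42, of which only 9.52% were higher. Floor 16 gave 84 with 28.6% higher, and offset 64 gave 244 with 32.4% higher. Quantile normalization gave 251 with 43.0% higher. The plain equal-variance test gave 1 (5685 at unadjusted p under 0.05), and leaving out each array gave 0 to 10, with fewer samples. With the replicate block limma gave 0 (6752 at unadjusted p under 0.05); arrays sharing a number had deviation correlations of only 0.019, 0.019 and 0.0019, and not every array correlated best with its own number. Where no construction is named, the cause was not tested.

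The Med12 difference of -2.17 passed with the trended, robust prior, with both filters, with both together and at the threshold of 0.1; it ranged from -2.54 to -1.77 without 1 array. Of the gene lists, 0 passed in camera with estimated correlation, against 22, and 15 to 23 under the other settings. Of the list values under these alternatives, 631 kept direction and side of the threshold, 60 lost the call, 8 gained it and 14 turned.

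The turned values, whose cause was not tested, were these. Cdk8 was at -0.037 with array weights and between -0.52 and 0.80 without 1 array, and Ccnc between -0.62 and 0.0571 without 1 array. Il5ra was at 0.17 with median centring, 0.13 with quantile and 0.14 with loess normalization, and between -0.24 and 0.10 without 1 array; Lum was at 0.0228 with median centring. Adjusted p values of turned lists were 0.772 (median centring), 0.940 (fry) and 0.322 to 0.961 (without 1 array) for p53 targets, 0.927 (quantile) and 0.812 (loess) for glycolysis, and 0.927, 0.812, 0.975 (50% filter) and 0.938 (fry) for the unfolded protein list. They were 0.982 (fry), 0.825 (mean of probe sets) and 0.407 to 0.975 (without 1 array) for stromal genes, and 0.0137 to 0.996 (without 1 array) for HSC-associated genes. Genes near a signal of 0 carry little order, and 41.6% to 49.5% of probe sets lay under 16.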

Other observations

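The genes in this part, apart from Hspa1b, were chosen after their values were seen. Several genes outside the lists rose in Med12 knockouts. Alad, an enzyme of haem synthesis, rose from 276 ± 26.9 to 828 ± 191 (SD, n = 3 each; log2 1.51; adjusted p = 0.0424). The mitochondrial transporter gene Abcb10 rose by 1.58 (adjusted p = 0.0314), the tetraspanin gene Tspan33 by 2.35 (adjusted p = 0.0381) and the lipid transporter gene Mfsd2b by 1.38 (adjusted p = 0.0314).

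Other genes outside the lists fell. Mpeg1, a pore-forming protein of macrophages, fell from 680 ± 268 to 47.0 ± 21.4 (SD, n = 3 each; log2 -3.44; adjusted p = 0.0349). H2-Ob, a class II antigen-loading chaperone, fell by 2.92 (log2), Ms4a6b by 2.33, Gimap7 by 2.13 and the chemokine receptor Ccr1 by 2.05. The transcription factors Bcl6 (-1.78; adjusted p = 0.0343) and Rel (-1.73; adjusted p = 0.0314) fell, as did the interleukin-10 receptor Il10ra (-1.69) and the DNA-sensing adaptor Sting1 (-1.68). The heat shock genes Hspa1a (2.30; adjusted p = 0.205) and Hspa1b (3.89; adjusted p = 0.131) did not pass over all genes, and their mean signals were 37.9 ± 42.4 and 63.3 ± 92.8 in controls and 232 ± 163 and 783 ± 483 in knockouts.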
